A study of Homo sapiens with 42 samples.

How the data were processed

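RNA was measured by stranded total RNA sequencing in human acute myeloid leukaemia cell lines treated with decitabine, a cytidine analogue that traps DNA methyltransferases, or with the solvent DMSO. Per the labels' protocols, cells were seeded at 100000 cells per mL, cells received 3 doses of decitabine (100 nM), the first at day 0, then at day 1 and day 2, and RNA was collected at 72 hours with an RNeasy kit. Libraries were made with a SMARTer stranded total RNA kit after ribosomal RNA removal with RiboGone, and read as single-end reads of 50 bp, per the labels' protocols. The labels describe 42 libraries of 7 lines, in 3 replicates per line and treatment. The deposited table holds columns for 5 of these lines: KG-1, MOLM-13, MOLM-14, OCI-AML3 and SKM-1. The 12 labelled libraries of OCI-AML2 and THP-1 have no column of their own in the table and were not analysed here. The table also has 12 HL-60 columns that belong to no labelled sample, and these were not used here. The series' design text does not name MOLM-14 among its lines, so that this identity rests on the sample labels and column names. The labels of SKM-1 and MOLM-13 name their columns. The columns of KG-1, MOLM-14 and OCI-AML3 were matched by line, treatment letter and replicate number, with the letters read as they are used for SKM-1 and MOLM-13.

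The submitters' processing notes list Salmon 1.2.1, STAR, featureCounts, DESeq2 and limma with the genome build hg38, without the role or the order of each. The deposited values were treated as a signal per gene: per the name the authors gave the table, they are estimated counts divided by DESeq2 normalization factors. They are not log-transformed and are here called normalised counts. Between 44.2% and 68.7% of the low values of a library were whole multiples of its step within a tolerance of 0.02, so whole reads could not be recovered and no count model was run. Depth was estimated as each library's total divided by that step. In units of 1e+06 reads in genes it ranged from 1.97 to 75, and replicate 2 of both arms of KG-1, MOLM-14 and OCI-AML3 was shallow (6 libraries). The table has 60240 genes with versioned Ensembl identifiers and gene names. Its annotation release is not stated; names and coordinates (GRCh38) were taken by unversioned identifier from GENCODE 29, which matched 58064 genes of the table and 21639 of the genes tested. The strand setting of the counting is not stated either, so values of antisense genes are uncertain.

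Values were analysed as log2(normalised count + 1). Genes with a value of at least 10 in at least 3 libraries were tested (22168 genes, 15127 of them protein-coding). A linear model with 10 group means, 1 per line and treatment, was fitted with limma 3.58.1 (R 4.3.3, statmod 1.5.0), with 20 residual degrees of freedom and moderated variances with a trend and robust estimation. All 30 libraries therefore share 1 estimate of the spread per gene. The contrasts were decitabine minus DMSO in each line, the mean of these 5 differences (the panel mean), an F-test of whether the differences are equal between lines, and the difference between MOLM-13 and MOLM-14. P-values were Benjamini-Hochberg adjusted over the tested genes within each contrast, and a gene was called at an adjusted p below 0.05. A fold change is on the log2(value + 1) scale and understates the change of low genes. The p-values measure the spread between these libraries, which may be technical: the labels say that wells were seeded in duplicate or triplicate and not whether replicates are separate cultures.

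The design planned 7 lines, of which 5 could be analysed. The comparisons and their tests, the gene lists, the naming rule and the alternatives were chosen before the data were examined. Added after seeing the data were 3 alternatives (library weights, a fit without the 6 shallow libraries, and scaling to the total without mitochondrial genes) and the tests that the closing section names as such. The 20 gene lists were cancer-testis and germline genes, interferon-stimulated genes, double-stranded RNA and DNA sensors, p53 targets, mitosis, DNA replication, DNA methylation machinery, decitabine uptake and metabolism, RNA decapping and decay, the m6A pathway, cholesterol synthesis, MHC class I, MHC class II, genes silenced by promoter methylation in tumours, imprinted genes, apoptosis regulators, the integrated stress response, inflammatory NF-kB targets, histones, and immune checkpoint ligands and receptors. The 8 marker lists covered monocytes and macrophages, granulocytes, haematopoietic progenitors, erythroid cells, megakaryocytes, lymphoid cells, epithelium and fibroblasts. Counts of a list are of the members that passed the filter, such as 30 of 41 cancer-testis, 5 of 16 erythroid and 9 of 15 checkpoint genes. A gene silent in DMSO can pass through the 3 decitabine libraries of 1 line where it is high. The share of members that rose and the list p-values may therefore overstate a rise. Each list was compared with the other genes by camera with a preset correlation of 0.01, adjusted over the 28 lists of each contrast, and again with a correlation estimated from the residuals. Fry was run as well, adjusted in the same way. It tests whether the members of a list change and does not compare them with the other genes.

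Genes were named by a fixed rule. It took the 12 called genes with the largest rise and the 12 with the largest fall of the panel mean, with the same sign in all 5 lines and a mean value of at least 20; 5 of each direction per line, whose decitabine and DMSO libraries do not overlap; the 8 with the widest range over lines among those that passed the F-test; 4 of each direction for MOLM-13 against MOLM-14; members of the lists; and always DNMT1, DCK, CDA, SAMHD1 and SLC29A1. Genes with clone-based names were left out, and 3 list members are not reported singly, though they stay in the lists and counts. Mitochondrial shares, a single value per library, were compared with exact permutation tests. Scripts were tested on simulated data with 200 changed genes per comparison, on 21230 genes. For the panel mean, 73.1% of genes changed 1.5-fold and 98.5% of those changed 4-fold were recovered, with 8 unchanged genes called. Single lines recovered 22.4% to 37.3% at 1.5-fold and 75.8% to 83.3% at 4-fold, and unchanged genes were called in KG-1 (44), MOLM-14 (122) and OCI-AML3 (102). At 1.5-, 2- and 4-fold KG-1 recovered 19, 28 and 53 genes and MOLM-14 25, 29 and 54. OCI-AML3 recovered 16, 28 and 55. In these lines unchanged genes were thus a larger share of the calls than an adjusted p below 0.05 allows. Alternatives tried were other pseudocounts, filters and scalings, a replicate block, each line's libraries alone, leaving out each library, each line and each set of lines registered together, lines as replicates, and the 3 added ones. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.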

Results

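RNA from 5 human acute myeloid leukaemia (AML) cell lines was compared after decitabine or DMSO, with 3 libraries per line and treatment and 30 libraries in all. KG-1, MOLM-13, MOLM-14, OCI-AML3 and SKM-1 are established lines, and MOLM-13 and MOLM-14 are sister lines from the same patient. MOLM-14 is named by the sample labels but not by the series' design text, and comparisons of the pair rest on these labels. The deposited values were normalised counts, here compared on the log2(value + 1) scale with limma. Libraries of MOLM-13 and SKM-1 were deep, with 42.9 to 75 (units of 1e+06 estimated reads in genes) in MOLM-13 and 50.9 to 69.3 in SKM-1. Those of KG-1 ranged from 2.97 to 31.2, those of MOLM-14 from 1.97 to 17.3 and those of OCI-AML3 from 2.51 to 25.9. Replicates correlated across genes with r between 0.918 and 0.975 in these 3 lines, and between 0.987 and 0.992 in MOLM-13 and SKM-1 (genes are not independent replicates).

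The share of the total value taken by mitochondrial genes was higher after decitabine, by 2.68 percentage points on the mean over the 5 lines (exact two-sided permutation test within lines, p = 1.3e-05). It went from 13.5% ± 0.896 to 18.7% ± 0.473 in MOLM-13, from 8.65% ± 0.533 to 10.9% ± 0.551 in MOLM-14 and from 14.5% ± 0.721 to 16.9% ± 1.35 in SKM-1 (SD, n = 3, exact permutation p = 0.1 in each line, the smallest that 3 against 3 libraries allow). In OCI-AML3 it went from 9.62% ± 1.23 to 12.4% ± 2.91 (SD, n = 3, exact permutation p = 0.2), and in KG-1 from 11.3% ± 0.85 to 12.1% ± 0.436 (SD, n = 3, exact permutation p = 0.3). Most of this share was mitochondrial ribosomal RNA (6.78% to 16.8% of a library), while mitochondrial mRNAs took 1.15% to 2.23%. The mRNA share of DMSO and decitabine libraries did not overlap in MOLM-13 (1.40% to 1.63%, and 2.16% to 2.23%) and MOLM-14. It overlapped in KG-1, OCI-AML3 and SKM-1 (in SKM-1 1.51% to 1.74%, and 1.45% to 1.72%).

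**Figure D1:**
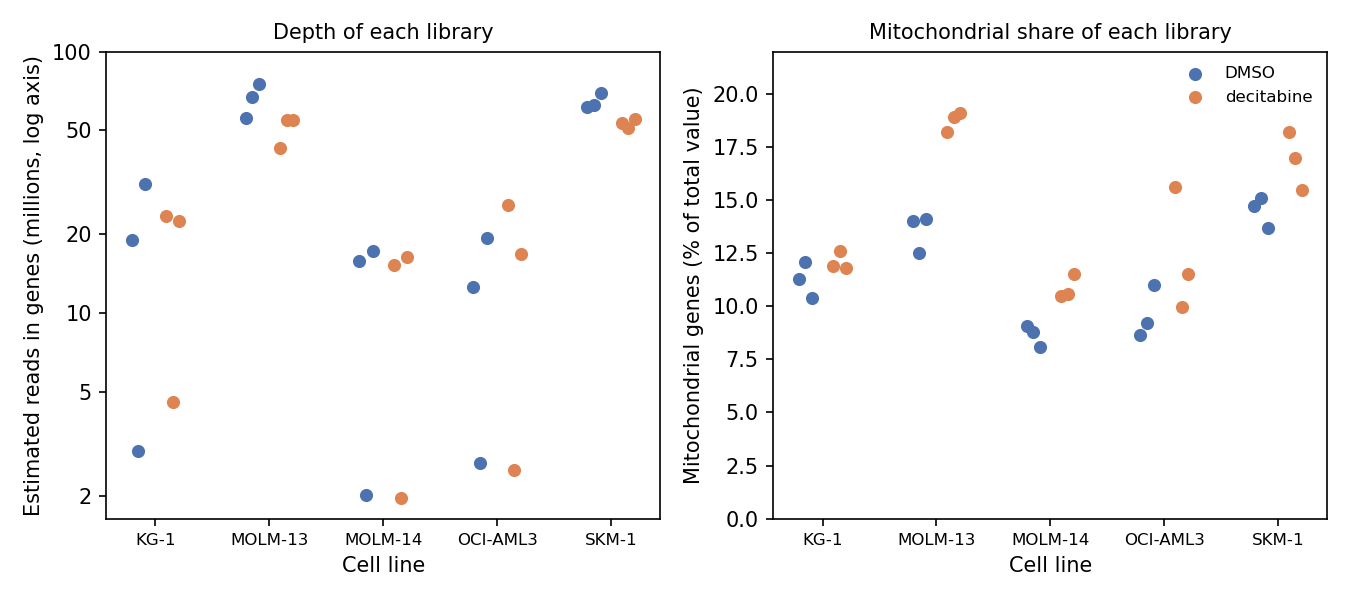
Estimated reads in genes (left, in units of 1e+06, log axis) and the mitochondrial share of the total value (right, in percent) of each library, by cell line, with DMSO and decitabine libraries as points of different colour. Replicate 2 of both arms lies far below the others in KG-1, MOLM-14 and OCI-AML3, and every decitabine library of MOLM-13 has a higher mitochondrial share than every DMSO library of that line.

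Which genes decitabine changed across the panel was asked of the mean difference over the 5 lines. The largest rise was that of PNMA5 (ENSG00000198883.12, GRCh38 chromosome X, 152988824 to 152994127), a gene of the paraneoplastic Ma antigen family, with a mean log2 fold change of 5.75 (SE 0.19) and values from 1.54 in MOLM-13 to 8.66 in SKM-1 (limma, BH-adjusted p = 9.66e-17). TKTL1, a transketolase-like gene, rose by 4.13 (SE 0.34) and ZNF595, a zinc finger gene, by 3.78 (SE 0.16) on the log2 scale (limma, BH-adjusted p = 2.98e-09 and 2.12e-14). Several of the genes that rose most are used in germ cells: TDRD9, a helicase of the piRNA pathway (3.50), HORMAD1, a protein of meiotic chromosomes (3.18), H1-6, the testis linker histone (3.14), and MAGEB2 (2.99). KRT8, a keratin of simple epithelia, rose by 3.49, DNAH8, a dynein of cilia and sperm tails, by 4.03, MYO18B by 3.23, the linker histone gene H1-1 by 2.98 and the potassium channel gene KCNH2 by 2.97.

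The falls of the panel mean were smaller. TERT, the catalytic subunit of telomerase, had a mean log2 fold change of -1.86 (SE 0.25, limma, BH-adjusted p = 4.23e-06), from -0.33 in MOLM-13 to -2.76 in MOLM-14. SLC7A5, a transporter of large neutral amino acids, had -1.12 (SE 0.08, limma, BH-adjusted p = 1.68e-10), ASNS, asparagine synthetase, -0.94 (SE 0.10, limma, BH-adjusted p = 1.51e-07), and PHGDH, which starts serine synthesis, -0.90. The other genes named for the largest falls were the hormone genes ADM2 (-1.38) and STC2 (-1.36), MANEAL (-1.27), SLITRK2 (-1.07), WWC1 (-1.02), SMN2 (-0.99), TMEM231 (-0.99) and FBRSL1 (-0.86). SMN2 has the near-identical copy SMN1, its value is therefore uncertain, and its call was lost with library weights (limma, BH-adjusted p = 0.158) and without the 6 shallow libraries (limma, BH-adjusted p = 0.082), as well as without MOLM-13, MOLM-14 or SKM-1 (limma, BH-adjusted p = 0.0575, 0.0778 and 0.0807). Other calls were lost without single lines: SLITRK2 without KG-1, MANEAL without SKM-1 and FBRSL1 without OCI-AML3 (-0.72, -0.91 and -0.79, limma, BH-adjusted p = 0.168, 0.127 and 0.055). In KG-1, MOLM-14 and OCI-AML3 alone SLITRK2, SMN2, MANEAL, TMEM231 and FBRSL1 were not called (limma, BH-adjusted p = 0.101, 0.199, 0.317, 0.0982 and 0.0501). In MOLM-13 and SKM-1 alone SLITRK2, SMN2 and FBRSL1 were not (limma, BH-adjusted p = 0.075, 0.105 and 0.257). All 24 genes named here moved in the same direction in all 5 lines, as the naming rule requires.

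Cancer-testis and germline genes, which DNA methylation silences in most adult tissues, rose on the panel mean. Of 41 listed members 30 passed the filter. Of these 30 members 20 rose and the other 10 were not called (23 rose when adjusted over the list alone, a count given in brackets for each list below), with a median log2 fold change of 1.13 (camera, BH-adjusted p = 3.03e-17). The lines differed: limma called 23 members in SKM-1, 7 in OCI-AML3 and 3 in KG-1. It called 0 in MOLM-13 (1 at an unadjusted p below 0.05, median 0.06, camera, BH-adjusted p = 0.577) and 0 in MOLM-14 (5 at an unadjusted p below 0.05, median 0.18, camera, BH-adjusted p = 0.407). The response of 18 of the 30 differed between lines (limma F-test, BH-adjusted p below 0.05). On the mean MAGEA4 had 3.39 (SE 0.25), DAZL, a germ cell RNA-binding protein, 2.51 (SE 0.23) and PRAME 1.84 (SE 0.19). The MAGEA, GAGE, CT45 and SSX families hold near-identical copies, and values of single members are uncertain. Of 14 imprinted genes, 4 rose and GRB10 fell (5 rose and 1 fell when adjusted over the list alone, median 0.14, camera, BH-adjusted p = 0.0801). The noncoding RNA gene H19 had 3.79 (SE 0.20) and DLK1 1.36. The call of GRB10 was lost without MOLM-14 (limma, BH-adjusted p = 0.162) and that of DLK1 without SKM-1 (0.75, limma, BH-adjusted p = 0.132). Of 17 genes silenced by promoter methylation in tumours, 2 rose and MGMT, a DNA repair gene, fell (the same counts when adjusted over the list alone, median 0.31, camera, BH-adjusted p = 0.278). SOCS1 was among those that rose (0.91, SE 0.15), though not in MOLM-13 and SKM-1 alone (limma, BH-adjusted p = 0.065).

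Markers of monocytes and macrophages rose most broadly among the marker lists. Of 22 markers 16 rose and the others were not called (16 when adjusted over the list alone), with a median of 0.96 (camera, BH-adjusted p = 1.08e-13). The list has 23 markers: CD14 stayed below the filter, with a highest value of 5.362 in any library. S100A9, a calcium-binding protein of myeloid cells, rose in each of the 5 lines and by 1.72 (SE 0.11) on the mean. S100A8 had 2.05 (SE 0.22), the costimulatory receptor CD86 1.84 (SE 0.10) and lysozyme (LYZ) 0.97 (SE 0.04). Of 13 granulocyte markers 6 rose and the others were not called (7 over the list alone, median 0.67, camera, BH-adjusted p = 0.000248). They included MPO, myeloperoxidase (1.40, SE 0.30), and PRTN3, proteinase 3 (0.50), which fell in SKM-1. Without KG-1, MPO had 0.87 and was not called (limma, BH-adjusted p = 0.101). Of 7 megakaryocyte markers 4 rose (4 over the list alone, median 0.70, camera, BH-adjusted p = 0.00995). Of 16 lymphoid markers 6 rose (7 over the list alone, median 0.60, camera, BH-adjusted p = 0.00116). Of 7 epithelial markers KRT8, KRT18 and KRT19 rose (3 over the list alone, median 0.22, camera, BH-adjusted p = 0.00321). Without SKM-1, KRT19 had 0.00 (limma, BH-adjusted p = 1.0). Without that line the epithelial, lymphoid and megakaryocyte lists were not called (camera, BH-adjusted p = 0.339, 0.0686 and 0.0678), nor in KG-1, MOLM-14 and OCI-AML3 alone (camera, BH-adjusted p = 0.489, 0.0553 and 0.072). Granulocyte markers were not called in MOLM-13 and SKM-1 alone (camera, BH-adjusted p = 0.255). Among 15 progenitor markers 2 rose and 3 fell (3 and 3 over the list alone, median 0.09, camera, BH-adjusted p = 0.823). The transcription factor GATA2 had 1.22 and HOXA10 -0.34. Erythroid markers (2 of 5 rose, 2 over the list alone, median -0.15, mean 0.25, camera, BH-adjusted p = 0.611) and fibroblast markers (2 of 5 rose, 2 over the list alone, median 0.40, camera, BH-adjusted p = 0.116) were not called as lists. GATA1, the erythroid transcription factor, rose by 1.75 (SE 0.21), with 1.01 in KG-1, MOLM-14 and OCI-AML3 alone (limma, BH-adjusted p = 0.121).

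Genes of immune recognition rose as well. Of 15 MHC class I genes 8 rose and the others were not called (10 over the list alone, median 0.34, camera, BH-adjusted p = 2.89e-05). HLA-B rose by 0.68 (SE 0.08) and HLA-C by 0.68 (SE 0.09) on the mean. Of 12 MHC class II genes 7 rose (9 over the list alone, median 0.58, camera, BH-adjusted p = 0.000109), a call lost without SKM-1 (camera, BH-adjusted p = 0.0678) and in KG-1, MOLM-14 and OCI-AML3 alone (camera, BH-adjusted p = 0.178). The invariant chain gene CD74 had 0.40. Interferon-stimulated genes were mixed. Of 30 genes 15 rose, such as IRF7 (0.81, SE 0.09) and IFI6 (0.76, SE 0.09), while USP18 (-0.37) and CMPK2 (-0.46) fell (16 and 2 over the list alone, median 0.25, camera, BH-adjusted p = 0.000276). In OCI-AML3 the list had a median of -0.17, with 1 gene higher and 2 lower (2 and 4 over the list alone, camera, BH-adjusted p = 0.0754). Of 12 sensors of double-stranded RNA and DNA, STING1 rose (0.36) and EIF2AK2, the kinase PKR, fell (-0.17), with the same counts over the list alone (median 0.03, against a camera direction of down, camera, BH-adjusted p = 0.844). Inflammatory NF-kB targets rose in 11 of 16 cases (12 over the list alone, median 0.71, camera, BH-adjusted p = 4.84e-07), among them TNF (1.45, SE 0.16) and NFKB2 (0.76, SE 0.10). In KG-1, MOLM-14 and OCI-AML3 alone TNF (0.76) and STING1 were not called (limma, BH-adjusted p = 0.117 and 0.172). Of 9 immune checkpoint ligands and receptors 4 rose (4 over the list alone, median 0.34, camera, BH-adjusted p = 0.0403, and adjusted p = 0.0523 with an estimated correlation), among them SIRPA, the receptor of CD47, at 0.53, with 0.09 in MOLM-13 and SKM-1 alone (limma, BH-adjusted p = 0.0545). The call of the checkpoint list was lost without KG-1 decitabine replicate 3 (camera, BH-adjusted p = 0.0537), MOLM-14 DMSO replicate 1 (0.055) or 3 (0.0603), MOLM-14 decitabine replicate 2 (0.0526) or OCI-AML3 DMSO replicate 3 (0.0602). It was also lost without KG-1 (0.0604), MOLM-14 (0.0961) or SKM-1 (0.0623), in KG-1, MOLM-14 and OCI-AML3 alone (0.0658) and in MOLM-13 and SKM-1 alone (0.229).

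Growth and stress genes moved in opposite directions by group. Of 24 p53 targets 12 rose and the others were not called (13 over the list alone, median 0.41, camera, BH-adjusted p = 1.57e-07). They included the antiproliferative gene BTG2 (1.06, SE 0.07), the cell cycle inhibitor CDKN1A (0.98, SE 0.10) and MDM2 (0.50, SE 0.04). Of 25 DNA replication genes 19 fell and the others were not called (22 over the list alone, median -0.23, camera, BH-adjusted p = 2.1e-14). MCM6, a subunit of the replicative helicase, fell in each line, with -0.55 (SE 0.04) on the mean. Of 25 mitosis genes 14 fell and UBE2C rose (15 and 1 over the list alone, median -0.14, camera, BH-adjusted p = 2.88e-07). The rise of UBE2C came from SKM-1, without which it had 0.03 (limma, BH-adjusted p = 0.894). The list rose in KG-1, as given below, and in KG-1, MOLM-14 and OCI-AML3 alone its median turned to 0.0286 and it was not called (camera, BH-adjusted p = 0.502). Cyclin A2 (CCNA2) had -0.46 (SE 0.04). The integrated stress response, which adapts amino acid supply and translation, was lower. Of 15 genes 8 fell and 2 rose (8 and 2 over the list alone, median -0.53, camera, BH-adjusted p = 9.75e-11). KG-1 went the other way, with a median of 0.10 and 1 gene higher (3 higher and 1 lower over the list alone, camera, BH-adjusted p = 0.169, fry, BH-adjusted p = 0.000447), and 11 of the 15 differed between lines (limma F-test). PSAT1 of serine synthesis had -1.01 (SE 0.05), CHAC1 -1.27 (SE 0.13) and the transcription factor ATF4 -0.53 (SE 0.04), while DNAJB9, a chaperone, had 0.62. Of 17 apoptosis regulators 6 rose and BCL2, an inhibitor of apoptosis, fell by 0.62 (7 and 1 over the list alone, median 0.19, camera, BH-adjusted p = 0.0607). Of 16 histone genes 7 fell and 1 rose (9 and 1 over the list alone, median -0.22, camera, BH-adjusted p = 0.00321, and adjusted p = 0.195 with an estimated correlation), a call also lost under quantile normalization (camera, BH-adjusted p = 0.0924).

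Genes of the drug's own pathway moved in both directions. The nucleoside transporter gene SLC28A3 rose by 2.05 (SE 0.36, limma, BH-adjusted p = 0.000179), with 4.75 in SKM-1, a call lost without that line (limma, BH-adjusted p = 0.0545) and in KG-1, MOLM-14 and OCI-AML3 alone (limma, BH-adjusted p = 0.349). DNMT1, the target enzyme, had a panel mean of -0.15 (SE 0.12, limma, BH-adjusted p = 0.447), and DCK, which phosphorylates decitabine, 0.02 (SE 0.13, limma, BH-adjusted p = 0.944). In MOLM-13 and SKM-1 alone, the lines with deep libraries, DCK fell by 0.29 (limma, BH-adjusted p = 0.000994). CDA, which inactivates the drug, rose by 0.90 (SE 0.22, limma, BH-adjusted p = 0.0041), and SAMHD1, a triphosphatase that hydrolyses its active form, by 0.25 (SE 0.07, limma, BH-adjusted p = 0.0124). SAMHD1 was not called without MOLM-13 (limma, BH-adjusted p = 0.113) or MOLM-14 (0.15, limma, BH-adjusted p = 0.215). In KG-1, MOLM-14 and OCI-AML3 alone SAMHD1, CDA, TET2 and IGF2BP2 were not called (limma, BH-adjusted p = 0.112, 0.11, 0.109 and 0.156). The uptake transporter SLC29A1 had -0.11 on the mean (limma, BH-adjusted p = 0.0929) and differed between lines (limma F-test, BH-adjusted p = 0.000428), with -0.69 in MOLM-14. In all, 5 of 15 uptake and metabolism genes rose and 3 fell (5 and 5 over the list alone, median 0.01, mean 0.18 and camera direction down, camera, BH-adjusted p = 0.823). Of 17 genes of the DNA methylation machinery 2 rose, among them TET2 (0.54), and 3 fell, among them UHRF1 (-0.18), with 2 and 4 over the list alone (median -0.08, mean 0.01, camera, BH-adjusted p = 0.278). Of 20 RNA decapping and decay genes 1 rose and 4 fell (the same over the list alone, median -0.07, camera, BH-adjusted p = 0.0275), a call lost under quantile normalization (camera, BH-adjusted p = 0.57) and without MOLM-14 DMSO replicate 2 (camera, BH-adjusted p = 0.0661). It was lost as well without MOLM-13 (0.0799) or SKM-1 (0.0678) and in KG-1, MOLM-14 and OCI-AML3 alone (0.215). PAN3, of a deadenylase complex, had -0.21. Of 18 m6A genes 3 fell, among them IGF2BP2 (-0.22), and the others were not called (3 over the list alone, median -0.02, camera, BH-adjusted p = 0.0628). The median turned to 0.0066 under quantile normalization and to 0.0090 under scaling without mitochondrial genes. Cholesterol synthesis genes had no common direction on the mean (2 of 19 rose and 2 fell, the same over the list alone, median -0.02, turning to 0.0076 under scaling without mitochondrial genes, camera, BH-adjusted p = 0.278).

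**Figure D2:**
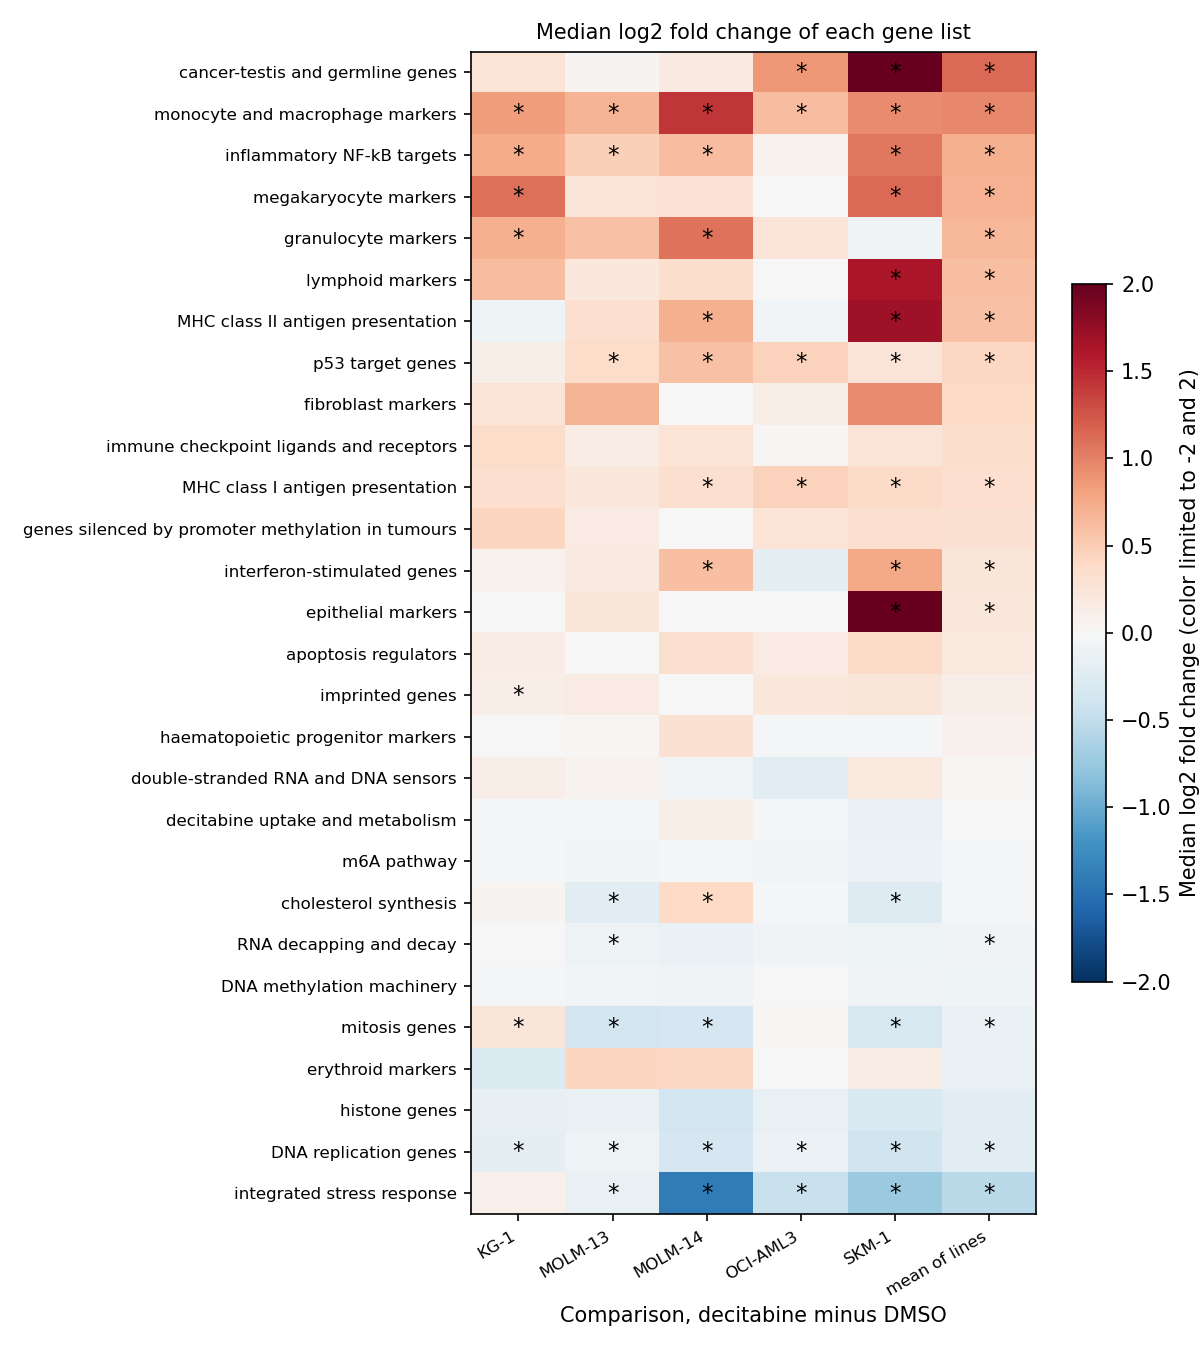
Median log2 fold change (decitabine minus DMSO) of each gene list in each line and on the mean of the lines, as colour limited to -2 and 2; an asterisk marks a list called by camera (BH-adjusted) with an estimated correlation. Monocyte markers are higher and DNA replication genes lower in all 5 lines, and the cancer-testis list is darkest in SKM-1, with a median of 3.81.

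In all, limma called 4333 of 22168 genes for the panel mean at a BH-adjusted p below 0.05, 2666 higher and 1667 lower; 780 were higher and 26 lower by at least 2-fold. The balance depended on scaling, with 2109 higher and 1871 lower under quantile normalization, and 3020 and 1299 when scaled without mitochondrial genes. The median SE of a gene's mean log2 fold change was 0.18. The mean describes these 5 lines: with the lines as replicates limma called 0 genes (3643 at an unadjusted p below 0.05, lowest BH-adjusted p = 0.0687). The count was 2315 without SKM-1, 1122 in KG-1, MOLM-14 and OCI-AML3 alone, and 8978 in MOLM-13 and SKM-1 alone, the lines with deep libraries. These sets were also registered in the repository at different times.

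In KG-1, PNMA5 went from 0.339 ± 0.587 to 268 ± 74.5 normalised counts (mean ± SD, n = 3, 208-fold, limma, BH-adjusted p = 2.5e-11), and COL14A1, a collagen gene, from 44.9 ± 14.6 to 5585 ± 384.5 (126-fold, limma, BH-adjusted p = 9.37e-09). CLC, the Charcot-Leyden crystal protein of eosinophils and basophils, rose 38.5-fold and HDC, which makes histamine, 13.5-fold. The granule enzyme MPO rose 11.4-fold, from 203.7 ± 33.6 to 2328 ± 321. TERT had a log2 fold change of -2.53 (limma, BH-adjusted p = 0.00638), which was not called from the line's own 6 libraries alone (limma, BH-adjusted p = 0.132).

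Monocyte markers rose in KG-1 (11 of 22, 11 over the list alone, median 0.83, camera, BH-adjusted p = 1.27e-11), as did granulocyte markers (4 of 13, 5 over the list alone, median 0.71, camera, BH-adjusted p = 0.000212). NF-kB targets (5 of 16, 6 over the list alone, median 0.75, camera, BH-adjusted p = 4.74e-05) and megakaryocyte markers (1 of 7, 3 over the list alone, median 1.10, camera, BH-adjusted p = 0.000956) rose too. Mitosis genes rose in this line (6 of 25, 9 over the list alone, median 0.25, camera, BH-adjusted p = 3.82e-07), with HMMR at 0.46 and TOP2A at 0.38. Replication genes were lower (2 of 25 fell, 4 over the list alone, median -0.17, camera, BH-adjusted p = 8.94e-06). Imprinted genes were higher (1 of 14, 4 over the list alone, median 0.13, camera, BH-adjusted p = 0.0186). The cancer-testis (median 0.27, turning to -0.08 under quantile normalization), lymphoid (median 0.62) and histone (median -0.17) lists passed camera (BH-adjusted p = 0.0442, 0.00502 and 0.0385) but not with an estimated correlation (adjusted p = 0.175, 0.0595 and 0.428). Limma called 838 genes in KG-1 at a BH-adjusted p below 0.05, 691 higher and 147 lower. The count was 105 from the line's own 6 libraries, whose spread includes the shallow ones, and 1278 without the shallow libraries.

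In MOLM-13, TKTL1 went from 2.56 ± 1.04 to 188 ± 8.80 normalised counts (mean ± SD, n = 3, 54.6-fold, limma, BH-adjusted p = 6.19e-05) and ZNF595 rose 19.6-fold (limma, BH-adjusted p = 6.44e-08). CEBPE, a transcription factor of late granulocyte development, rose 10.8-fold, from 6.87 ± 0.800 to 83.9 ± 3.19 (limma, BH-adjusted p = 0.00147), the endogenous retroviral gene ERV3-1 8.46-fold and the kinase gene SGK1 7.59-fold. PDGFA, a growth factor gene, fell 2.94-fold, from 850 ± 84.9 to 288 ± 15.8 (limma, BH-adjusted p = 4.38e-06). NREP (-1.25) and TWISTNB (-1.09) also fell in this line.

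Mitosis genes fell in MOLM-13 (11 of 25, 17 over the list alone, median -0.37, camera, BH-adjusted p = 8.3e-21), among them PLK1 (-0.59) and DLGAP5 (-0.58). Replication genes (2 of 25 fell, 3 over the list alone, median -0.10, camera, BH-adjusted p = 0.000365) and cholesterol synthesis genes were lower (2 of 19 fell, 2 over the list alone, median -0.23, camera, BH-adjusted p = 0.000109), with INSIG1 at -0.99. Monocyte markers (6 of 22 rose, 11 over the list alone, median 0.67, camera, BH-adjusted p = 1.12e-08), p53 targets (2 of 24, 5 over the list alone, median 0.37, camera, BH-adjusted p = 0.00045) and NF-kB targets (2 of 16, 2 over the list alone, median 0.48, camera, BH-adjusted p = 0.00326) were higher. The stress response (1 rose and 2 fell of 15, 1 and 3 over the list alone, median -0.15) and decapping lists (1 of 20 fell, 2 over the list alone, median -0.10) were lower (camera, BH-adjusted p = 0.0243 for both). The granulocyte (median 0.58), MHC class I (median 0.21) and histone (median -0.15) lists passed camera (BH-adjusted p = 0.0105, 0.0205 and 0.0205) but not with an estimated correlation (adjusted p = 0.108, 0.0802 and 0.316). Limma called 693 genes at a BH-adjusted p below 0.05, 322 higher (46.5%) and 371 lower. The share higher was 64.1% under quantile normalization, 57.7% under upper-quartile scaling and 67.6% when scaled without mitochondrial genes. The count depended on the fit: it was 4686 from the line's own 6 libraries and 5651 with library weights, though 284 under quantile normalization. It was 235 or 268 without DMSO replicate 1 or 2, and 236, 410 or 315 without decitabine replicate 1, 2 or 3.

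In MOLM-14, H19 rose from 28.2 ± 11.6 to 1487 ± 269 normalised counts (mean ± SD, n = 3, 52.9-fold, limma, BH-adjusted p = 5.24e-09). ASNS fell 6.12-fold, from 4630 ± 649.8 to 758.8 ± 133.8 (limma, BH-adjusted p = 1.56e-08), and SLC7A5 4.61-fold, from 7331 ± 1450 to 1612 ± 464.5 (limma, BH-adjusted p = 6.53e-09). SLC6A9, a glycine transporter, fell 42.6-fold, from 144 ± 36.1 to 3.44 ± 3.16 (limma, BH-adjusted p = 8.8e-05), and RPS6KA2 had a log2 fold change of -3.46. NR5A1, a nuclear receptor gene, had 55.5 ± 61.2 after decitabine and was listed at 0 in DMSO (limma, BH-adjusted p = 2.94e-06, BH-adjusted p = 0.061 in limma from the line's own 6 libraries).

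The integrated stress response was lower in MOLM-14 (9 of 15 fell and 1 rose, 12 and 2 over the list alone, median -1.40, camera, BH-adjusted p = 3.34e-15), with CHAC1 at -2.98, TRIB3 at -2.40 and PSAT1 at -2.24. Monocyte markers were higher (14 of 22 rose and 1 fell, 14 and 2 over the list alone, median 1.43, camera, BH-adjusted p = 1.17e-09), with S100A8 at 3.09 and CD86 at 2.39. So were granulocyte markers (2 of 13, 6 over the list alone, median 1.09, camera, BH-adjusted p = 0.000207). Interferon-stimulated genes (11 of 30 rose and 1 fell, 14 and 1 over the list alone, median 0.61, camera, BH-adjusted p = 6.07e-07), p53 targets (9 of 24, 13 over the list alone, median 0.59, camera, BH-adjusted p = 1.17e-09) and MHC class I genes (4 of 15, 7 over the list alone, median 0.32, camera, BH-adjusted p = 0.000773) rose. MHC class II genes (3 of 12, 6 higher and 1 lower over the list alone, median 0.72, camera, BH-adjusted p = 0.0164) and NF-kB targets (5 of 16, 7 higher and 2 lower over the list alone, median 0.61, camera, BH-adjusted p = 0.00763) were higher as well.

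Cholesterol synthesis genes rose in MOLM-14 (8 of 19, 11 over the list alone, median 0.40, camera, BH-adjusted p = 8.77e-05), with MSMO1 at 1.07 and HMGCS1 at 0.79. Mitosis (11 of 25 fell and 1 rose, 13 and 1 over the list alone, median -0.34, camera, BH-adjusted p = 3.23e-07) and replication genes (8 of 25 fell, 18 over the list alone, median -0.34, camera, BH-adjusted p = 5.33e-10) were lower. Histone genes had a median of -0.38 (5 of 16 fell and 1 rose, 7 and 1 over the list alone, camera, BH-adjusted p = 0.0122, and adjusted p = 0.335 with an estimated correlation). Limma called 2445 genes at a BH-adjusted p below 0.05, 1387 higher and 1058 lower. The count was 275 from the line's own 6 libraries. In the simulated data this line had 122 false calls, beside 25, 29 and 54 genes recovered at 1.5-, 2- and 4-fold. Its adjusted p-values may therefore be too small.

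In OCI-AML3, PNMA5 had 140 ± 16.5 and PNMA6E 119 ± 15.4 normalised counts after decitabine, and both were listed at 0 in DMSO (mean ± SD, n = 3, limma, BH-adjusted p = 4.5e-11 and 9.08e-12). MAGEA4 rose from 0.274 ± 0.475 to 124 ± 30.1 (log2 fold change 6.65, limma, BH-adjusted p = 2.12e-08) and CCDC152 98-fold. CD86 rose 9.33-fold, from 28.5 ± 2.19 to 275.1 ± 36.3 (limma, BH-adjusted p = 9.77e-10). TERT had a log2 fold change of -2.48 (limma, BH-adjusted p = 0.00634), a call lost without decitabine replicate 2 (-1.75, limma, BH-adjusted p = 0.0583). HOXA6, a homeobox gene, had -2.68 and APOL4 -3.36, and neither was called from the line's own 6 libraries (limma, BH-adjusted p = 0.468 and 0.351). TERT was not called from these either (limma, BH-adjusted p = 0.216), and with library weights neither TERT nor HOXA6 was (limma, BH-adjusted p = 0.147 and 0.103).

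Cancer-testis genes rose in OCI-AML3 (7 of 30, 7 over the list alone, median 0.86, camera, BH-adjusted p = 8.84e-08), as did p53 targets (7 of 24, 7 over the list alone, median 0.46, camera, BH-adjusted p = 1.49e-06). Monocyte markers (6 of 22, 9 over the list alone, median 0.62, camera, BH-adjusted p = 1.49e-06) and MHC class I genes (7 of 15, 9 over the list alone, median 0.46, camera, BH-adjusted p = 5.87e-06) rose as well, with HLA-C at 0.89 and HLA-B at 0.61. The integrated stress response (6 of 15 fell, with 6 lower and 1 higher over the list alone, median -0.45, camera, BH-adjusted p = 1.7e-06) and replication genes (2 of 25 fell, 2 over the list alone, median -0.11, camera, BH-adjusted p = 0.0149) were lower. The nucleic acid sensors passed camera with a median of -0.21 (2 of 12 fell, 4 over the list alone, BH-adjusted p = 0.0178) but not with an estimated correlation (adjusted p = 0.275). Limma called 1191 genes at a BH-adjusted p below 0.05, 828 higher and 363 lower. The count was 44 from the line's own 6 libraries, 640 with library weights and 2203 without the shallow libraries.

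In SKM-1, MAGEA4, a cancer-testis antigen gene, went from 1.01 ± 0.224 to 1156 ± 45.0 normalised counts (mean ± SD, n = 3, 579-fold, limma, BH-adjusted p = 1.8e-11). ZNF595 went from 1.76 ± 1.54 to 826 ± 53.9 (349-fold, limma, BH-adjusted p = 4.31e-14) and COL14A1 from 1.67 ± 1.62 to 963.6 ± 11.9 (404-fold, limma, BH-adjusted p = 2.73e-11). PNMA5 rose 405-fold, H19 52.4-fold and KRT8 154-fold. PRTN3, a neutrophil granule protease, fell 3.8-fold, from 11000 ± 1292 to 2903 ± 382 (limma, BH-adjusted p = 1.25e-06), and CCR2, the receptor of CCL2, 5.64-fold (limma, BH-adjusted p = 4.52e-08). LRP2 (-2.05), FRMD3 (-1.89) and MANEAL (-2.75) were also lower.

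Of the 30 tested cancer-testis and germline genes (41 listed) 23 rose in SKM-1 and the others were not called (26 over the list alone, median 3.81, camera, BH-adjusted p = 1.58e-41). Some of the 30 may have passed the filter only through their rise in this line. MHC class II genes (7 of 12, 11 over the list alone, median 1.69, camera, BH-adjusted p = 6.65e-10), NF-kB targets (6 of 16, 10 over the list alone, median 1.05, camera, BH-adjusted p = 9.63e-09) and interferon-stimulated genes (10 of 30, 13 over the list alone, median 0.76, camera, BH-adjusted p = 2.08e-07) rose, with TNF at 4.22, HLA-DRA at 2.17 and IRF7 at 1.90. Epithelial markers (3 of 7, 4 over the list alone, median 2.09, camera, BH-adjusted p = 1.08e-06) and lymphoid markers (6 of 16, 7 over the list alone, median 1.64, camera, BH-adjusted p = 3.18e-06) rose. Monocyte (10 of 22 rose and 1 fell, the same over the list alone, median 0.95, camera, BH-adjusted p = 3.2e-05) and megakaryocyte markers (2 of 7, 3 over the list alone, median 1.13, camera, BH-adjusted p = 0.00768) were higher. MHC class I genes (3 of 15, 5 over the list alone, median 0.38, camera, BH-adjusted p = 0.00545) and p53 targets were higher (6 of 24 rose and 1 fell, 8 and 2 over the list alone, median 0.26, camera, BH-adjusted p = 0.0289).

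Replication genes (11 of 25 fell, 17 over the list alone, median -0.40, camera, BH-adjusted p = 3.38e-12) and mitosis genes (14 of 25 fell and 1 rose, 16 and 1 over the list alone, median -0.33, camera, BH-adjusted p = 1.61e-11) were lower in SKM-1. The integrated stress response (8 of 15 fell, 10 over the list alone, median -0.75, camera, BH-adjusted p = 1.1e-11) and cholesterol synthesis genes (3 of 19 fell, 5 over the list alone, median -0.25, camera, BH-adjusted p = 0.000282) were lower as well. The mitosis gene that rose was UBE2C, a ubiquitin-conjugating enzyme, from 8.06 ± 2.94 to 87.9 ± 5.51 normalised counts (SD, n = 3, limma, BH-adjusted p = 1.99e-11). Apoptosis regulators passed camera (5 of 17 rose and 1 fell, 6 and 2 over the list alone, median 0.39, BH-adjusted p = 0.0318) but not with an estimated correlation (adjusted p = 0.0682). Limma called 1999 genes at a BH-adjusted p below 0.05, 1264 higher (63.2%) and 735 lower; the share higher was 73.6% when scaled without mitochondrial genes. The count was 7824 from the line's own 6 libraries and 8283 with library weights, and quantile normalization moved the median of all genes from 0.08 to -0.08.

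**Figure D3:**
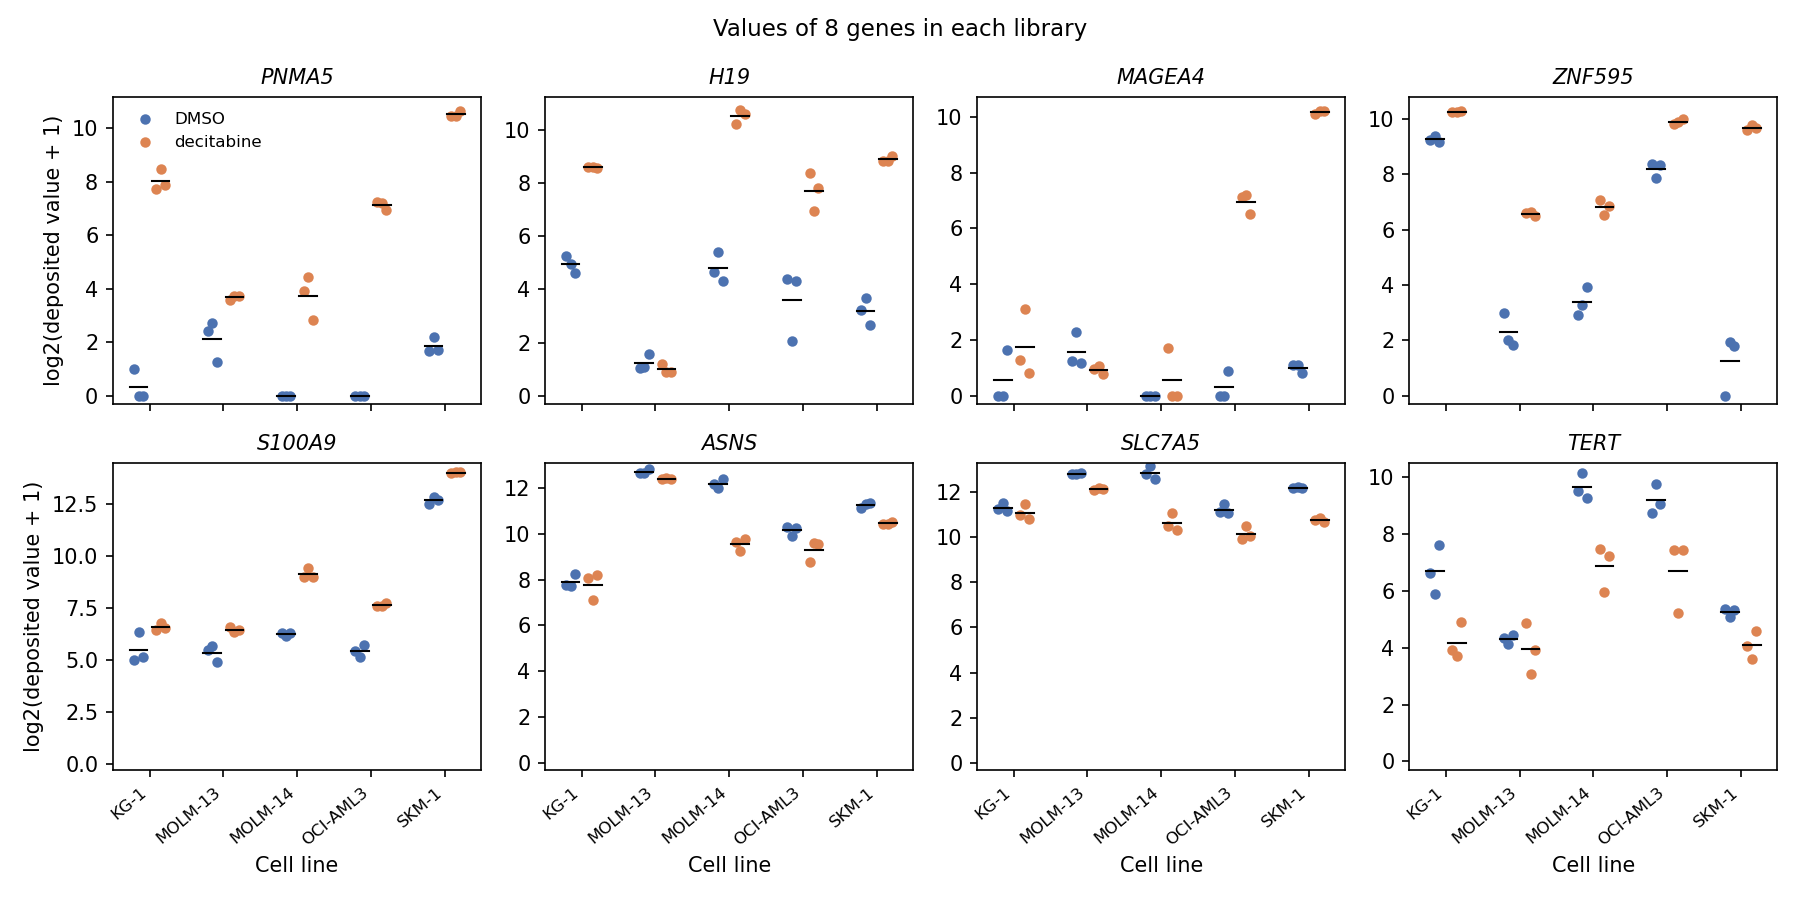
log2(normalised count + 1) of 8 genes in each library, by cell line; points are libraries, DMSO and decitabine in different colours, and black bars are means of 3 libraries. PNMA5 is higher after decitabine in all 5 lines, MAGEA4 in OCI-AML3 and SKM-1, and ASNS and SLC7A5 fall furthest in MOLM-14.

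How far the lines share a response was asked from the calls common to them. In all 5 lines 23 genes were called in the same direction, 17 higher and 6 lower, where independent lists would give 0.0013 and 6.4e-05. Among them were CD86, S100A9 and PNMA5, which rose, and MCM6, which fell. The largest overlaps of pairs in number were 319 genes higher and 312 lower in both MOLM-14 and SKM-1 (79.1 and 35.1 by chance). Next among higher genes were MOLM-14 and OCI-AML3 with 262 (51.8 by chance) and OCI-AML3 and SKM-1 with 259 (47.2 by chance). Among lower genes they were MOLM-13 and MOLM-14 with 170 (17.7 by chance) and MOLM-13 and SKM-1 with 137 (12.3 by chance). No control libraries are shared between lines. The spread per gene is shared, so calls are not independent between lines and the chance figures may be too low. Genes called in opposite directions numbered from 11 (MOLM-13 and SKM-1) to 48 (MOLM-14 and SKM-1) per pair. KG-1 and MOLM-13 had 21, beside 70 higher and 22 lower in both. The calls common to all lines fell to 14 under quantile normalization and rose to 62 without the shallow libraries. Leaving out a MOLM-13 library lowered the common count to 12, 15 and 15 (DMSO replicates 1, 2 and 3) and to 11, 14 and 14 (decitabine replicates 1, 2 and 3).

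The response differed between lines for 2096 genes (limma F-test, BH-adjusted p below 0.05, 5009 at an unadjusted p below 0.05). MAGEA4 had the widest range, from -0.63 in MOLM-13 to 9.18 in SKM-1 (limma F-test, BH-adjusted p = 6.21e-09). HDC had -1.44 in MOLM-14, 3.76 in KG-1 and 7.84 in SKM-1 (limma F-test, BH-adjusted p = 1.31e-08) and COL14A1 -0.30 in MOLM-14 and 8.66 in SKM-1. CD93, a receptor of myeloid and endothelial cells, had 7.83 in SKM-1 and between -0.01 and 0.43 elsewhere (limma F-test, BH-adjusted p = 2.18e-17). GPAT2 had 7.62 in SKM-1, 3.10 in OCI-AML3 and 0.00 in MOLM-14. LYZ rose in KG-1, MOLM-13, MOLM-14 and OCI-AML3 but had -0.06 in SKM-1 (limma F-test, BH-adjusted p = 7.75e-08). TRIB3, a stress response pseudokinase, had 0.87 in KG-1 and -2.40 in MOLM-14 (limma F-test, BH-adjusted p = 8.7e-10). Of the genes named for the panel 17 of 24 differed between lines, while TERT, for example, was not called (limma F-test, BH-adjusted p = 0.119). A p above the threshold does not show equal responses. Library weights gave 5794 differing genes and the fit without the shallow libraries 4789.

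The sister lines MOLM-13 and MOLM-14 responded differently in 318 genes, 141 with a higher and 177 with a lower log2 fold change in MOLM-13 (limma, BH-adjusted p below 0.05, 2855 at an unadjusted p below 0.05). ATF5, a transcription factor of the stress response, rose in MOLM-13, from 703 ± 25.7 to 2340 ± 90.4 normalised counts, and fell in MOLM-14, from 937 ± 98.9 to 363 ± 39.4 (SD, n = 3, difference 3.10, SE 0.24, limma, BH-adjusted p = 4.93e-08). CHAC1, which degrades glutathione, fell in MOLM-14 and had -0.15 in MOLM-13 (difference 2.83, SE 0.40, limma, BH-adjusted p = 0.00032). H19 had 5.73 in MOLM-14 and -0.23 in MOLM-13 (difference -5.96, SE 0.64, limma, BH-adjusted p = 6.2e-06). The DMSO means of the pair correlated across genes with r = 0.910, the highest of the 10 pairs of lines (0.823 to 0.893 for the others, genes are not independent replicates). Counts of calls are not comparable between these lines, whose depths differ: without the shallow libraries the pair differed in 1077 genes and with library weights in 1078. Without MOLM-13 DMSO replicate 1 or 2 the count was 172 or 159, and without MOLM-13 decitabine replicate 1, 2 or 3 it was 178, 194 or 177.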

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

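The tests of the mitochondrial share and of the number of calls in MOLM-13 and MOLM-14 were chosen only after the result was seen, as were the library weights and the fit without the 6 shallow libraries. What marks the results below is a difference between cell lines in the response to decitabine, tested with limma and BH-adjusted. The response differed between lines for 2096 genes, among them 17 of the 24 genes named for the panel and 44 of the 112 genes named from lists. MAGEA4 had the widest range of log2 fold changes, 9.81, from -0.63 in MOLM-13 to 9.18 in SKM-1. HDC ranged over 9.29, from -1.44 in MOLM-14 to 7.84 in SKM-1. COL14A1 ranged over 8.96, with 6.98 in KG-1 and 8.66 in SKM-1 against -0.30 in MOLM-14. CT45A5, a cancer-testis gene, ranged over 8.69, from -1.44 in OCI-AML3 to 7.24 in SKM-1 (limma F-test, BH-adjusted p = 1.74e-05). GAGE12F, of another cancer-testis family, ranged over 8.65, with 8.65 in SKM-1 and 1.46 in OCI-AML3 (limma F-test, BH-adjusted p = 1.5e-08). SLC6A9, the glycine transporter gene, ranged over 8.16, from -5.41 in MOLM-14 to 2.75 in SKM-1 (limma F-test, BH-adjusted p = 0.00055, and 0.0584 without MOLM-14). CD93 ranged over 7.84, with 7.83 in SKM-1, and GPAT2 over 7.62, with 7.62 in SKM-1 and 0.00 in MOLM-14. CT45A5 and GAGE12F have near-identical copies, so the values of these single members are uncertain.

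Between the sister lines MOLM-13 and MOLM-14 the response differed for 318 genes. ATF5 had a difference of 3.10 (MOLM-13 minus MOLM-14) and CHAC1 of 2.83, both higher in MOLM-13, and H19 had -5.96. SLC6A9 differed by 5.16 (SE 1.17, limma, BH-adjusted p = 0.0235). This call was lost without MOLM-13 DMSO replicate 1 (0.0566) or 2 (0.0632), MOLM-13 decitabine replicate 1 (0.0568), 2 (0.0549) or 3 (0.0541), MOLM-14 DMSO replicate 2 (0.0551) or MOLM-14 decitabine replicate 2 (0.0606). FAM111B differed by 2.81 (SE 0.64, limma, BH-adjusted p = 0.0246), lost without MOLM-13 DMSO replicate 1 (0.0544), 2 (0.0539) or 3 (0.0617), MOLM-13 decitabine replicate 1 (0.0543), 2 (0.0639) or 3 (0.0526), or MOLM-14 DMSO replicate 2 (0.0598). STAB1, a scavenger receptor gene, had -4.04 (SE 1.00, limma, BH-adjusted p = 0.0405). Its call was lost without MOLM-13 DMSO replicate 1 (0.0636), 2 (0.123) or 3 (0.0766), MOLM-13 decitabine replicate 2 (0.123) or 3 (0.066), MOLM-14 DMSO replicate 1 (0.0948), or MOLM-14 decitabine replicate 1 (0.0571), 2 (0.0557) or 3 (0.0753), and with a pseudocount of 0.5 (0.0677) or no filter (0.072). IGLL1, of the surrogate light chain of B cell precursors, had -3.55 (SE 0.81, limma, BH-adjusted p = 0.0238), lost without MOLM-13 DMSO replicate 1 (0.0672) or 2 (0.0585) or MOLM-13 decitabine replicate 1 (0.0694) or 2 (0.0622) and under quantile normalization (0.0893). ZNF615, a zinc finger gene, had -3.30 (SE 0.74, limma, BH-adjusted p = 0.0228). Its call was lost without MOLM-13 DMSO replicate 1 (0.079), MOLM-13 decitabine replicate 2 (0.0624) or 3 (0.0806), MOLM-14 DMSO replicate 1 (0.0589) or MOLM-14 decitabine replicate 2 (0.0571) and with a pseudocount of 10 (0.164).

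Other splits of the libraries into arms of the same size were counted. In each single line 1 of the 10 splits, the real one, gave as many genes, and with 10 splits the share is never under 0.1. The real split and the highest other gave 838 and 119 genes in KG-1, 693 and 1 in MOLM-13, 2445 and 488 in MOLM-14, 1191 and 231 in OCI-AML3, and 1999 and 2 in SKM-1. Over all lines, 100 splits within lines were drawn, and in each case below 1 split, the real one, gave as many genes. The panel mean had 4333 genes against 443 for the highest other split, the calls common to all lines 23 against 0, the differences between lines 2096 against 1426, and the differences between MOLM-13 and MOLM-14 318 against 148. For the panel mean and the common calls this argues against a difference between the arms by chance. Shuffling the arms changes the decitabine effect itself in every line, so for the differences between lines it does not test whether responses are equal.

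The first pattern weighed is the rise of 23 of the 30 tested cancer-testis and germline genes in SKM-1 (median 3.81). Cells of another panel line mixed into the decitabine libraries are excluded: genes abundant in that line and near 0 in SKM-1 DMSO reached a median of at most 1.13% of their level there (MOLM-13, 8 genes), and 0.212%, 0.0217% and 0.0172% for KG-1 (60 genes), MOLM-14 (32) and OCI-AML3 (31). The germline genes would need medians from 1150% (OCI-AML3) to 25900% (MOLM-14), and 23 of 23 lay above their level in KG-1, MOLM-13 and MOLM-14 and 22 of 23 above that in OCI-AML3. The authors' normalization is excluded too, as 22 members were called higher under quantile normalization and 23 under upper-quartile scaling. Reads shared between near-identical copies and cells from outside the panel were not tested, and a response of SKM-1 itself to decitabine may account for the rise but stays a hypothesis.

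The second pattern is the higher mitochondrial share after decitabine. A difference in depth between the arms is excluded as the whole cause, since with log2 depth in a linear model of the 30 libraries the difference was 2.69 points (SE 0.444), against 2.68 without it, though the decitabine libraries were on average shallower in 4 of 5 lines (ratios 0.771 to 0.959, and 1.31 in OCI-AML3). Less complete removal of ribosomal RNA would raise the mitochondrial ribosomal RNAs and leave the 13 mitochondrial mRNAs at the median of all genes: in MOLM-13 these mRNAs lay 0.52 above it (log2), which excludes that cause alone. In KG-1 the distance was -0.0193, so that this cause may account for a rise there. The rise in KG-1 was itself not shown, however (exact permutation test, p = 0.3). In MOLM-14 (0.13), OCI-AML3 (0.29) and SKM-1 (-0.38) the distance decides neither way. In SKM-1 the rise lay in the ribosomal RNAs (12.1% to 13.4% of a library in DMSO, 14% to 16.5% after decitabine). The mRNA share did not rise there (1.51% to 1.74%, and 1.45% to 1.72%). Of the ribosomal RNAs MT-RNR1 rose in OCI-AML3 (2.81, limma, BH-adjusted p = 0.0207) and MT-RNR2 in MOLM-13 (0.49, limma, BH-adjusted p = 0.0373). A response of mitochondrial RNA to decitabine was not tested apart from these and stays open.

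The third pattern is the lower count in MOLM-13 (693) than in its sister line MOLM-14 (2445). Noise of the shallow MOLM-14 libraries stays open as the cause of the gap: without the 6 shallow libraries MOLM-14 had 3113 calls and MOLM-13 2672, but this also narrowed the spread shared by all lines, and from their own 6 libraries MOLM-14 had 275 and MOLM-13 4686. In simulated data 122 unchanged genes were called in MOLM-14 and 0 in MOLM-13, so noise between replicates can add calls in MOLM-14. How much of the gap it makes was not shown. The spread pooled with shallower libraries may account for the lower count, since with library weights MOLM-13 had 5651 calls and MOLM-14 2048. In simulated data weights also lowered the recovery of 1.5-fold changes in MOLM-14, from 37.3% to 11.9%, and its unchanged genes called, from 122 to 11. In MOLM-13 unchanged genes called rose from 0 to 34. A library batch cannot be told apart from the line, because the lines were registered in the repository in separate sets and no line is in both, and the correlation of the pair's DMSO means (r = 0.910) does not decide it. A different response of the lines stays open.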

How the results depend on the processing

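The library weights, the fit without the 6 shallow libraries and the scaling without mitochondrial genes were chosen only after the result was seen. The spread per gene is shared by all 30 libraries, so shallow libraries of KG-1, MOLM-14 and OCI-AML3 widen the error of MOLM-13 and SKM-1. The same sharing narrows the error of KG-1, MOLM-14 and OCI-AML3. The variance of fold changes from the spread between replicates was 0.4553, 0.6937 and 0.5666 in these lines. It was 0.1004 in MOLM-13 and 0.0848 in SKM-1, yet the median SE of a fold change was 0.3920 in each line. Adjusted p-values within KG-1, MOLM-14 and OCI-AML3 may therefore be too small. In simulated data with 1.5-fold changes, library weights raised recovery from 23.9% to 73.1% in MOLM-13 and from 22.4% to 77.6% in SKM-1. Unchanged genes called rose there from 0 to 34 and from 0 to 43, a larger share of the calls than an adjusted p below 0.05 allows. Weights lowered recovery from 28.4% to 22.4% in KG-1, from 37.3% to 11.9% in MOLM-14 and from 23.9% to 13.4% in OCI-AML3. Unchanged genes called fell as well, from 44 to 17, from 122 to 11 and from 102 to 16. EdgeR and DESeq2, planned for the case that counts could be had, were not run, nor was any alternative for OCI-AML2 and THP-1. Replicate numbers were not taken to pair the arms, as the labels give the number no meaning and 6 of 15 pairs, not all, correlated above 0.1 (from -0.0225 to 0.1526). As a hint from the data, all 9 pairs of KG-1, MOLM-14 and OCI-AML3, whose replicate 2 is shallow in both arms, correlated best with their own number in both directions, against 2 of the 6 in MOLM-13 and SKM-1, so a structure shared by number stays open in the first 3 lines. With the replicate block every count stayed within 1.5 times, with 943 genes in KG-1, 2686 in MOLM-14, 1400 in OCI-AML3 and 4877 for the panel, and the checkpoint list was lost (camera, BH-adjusted p = 0.0564). Of 198 values of named genes 9 calls were lost under it and 4 gained, and among those lost were the differences between MOLM-13 and MOLM-14 of SLC6A9 (limma, BH-adjusted p = 0.0862), FAM111B (0.0748) and STAB1 (0.0928). With fry, which does not compare a list with the other genes, 24 of 28 lists were called for the panel mean. Camera, which does, called 17, and 15 with an estimated correlation. Over all alternatives, 7092 of 7671 values of named genes kept direction and side of the threshold, 482 lost the call, 72 gained it and 25 reversed. For lists these were 1251, 34, 25 and 33 of 1343.

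The cause of the following was not tested unless given. Without a filter MOLM-13 and MOLM-14 differed in 211 genes. Under the stricter filter 3 cell type marker lists were called, not 5. It left 27 of the 28 lists to test, and 3 of these lost their call. Quantile normalization gave 284 genes in MOLM-13 and 14 common to all lines. From a line's own 6 libraries, where the spread is its own, the counts were 105 (KG-1), 4686 (MOLM-13), 275 (MOLM-14), 44 (OCI-AML3) and 7824 (SKM-1). With the 5 lines as replicates, a fit with only 4 degrees of freedom, limma called 0 genes for the panel (3643 at an unadjusted p below 0.05) and 0 of the named genes. Of the 28 lists, 26 kept direction and side of the threshold there and 2 lost their call. Without KG-1, 2 of the 28 lists lost their call, the checkpoint list among them. Without SKM-1 the panel had 2315 genes, 9 gene lists (12 with all lines, with MHC class II, checkpoint and decapping lost) and 2 marker lists (epithelial, lymphoid and megakaryocyte lost). KG-1, MOLM-14 and OCI-AML3 alone gave 1122 genes, 59 called named genes (110 with all lines), 8 gene lists (the same 3 and mitosis lost) and 2 marker lists (the same 3 lost). MOLM-13 and SKM-1 alone gave 8978 genes. Library weights, which lower the share of noisy libraries, gave 5651 (MOLM-13), 640 (OCI-AML3), 8283 (SKM-1), 1078 (MOLM-13 against MOLM-14), 53 (common) and 5794 (differing between lines). Without the 6 shallow libraries these were 1278 (KG-1), 2672 (MOLM-13), 2203 (OCI-AML3), 4610 (SKM-1), 1077, 62 and 4789.

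Leaving out 1 library gave 607 to 937 genes in KG-1, 235 to 545 in MOLM-13, 1660 to 2601 in MOLM-14, 821 to 1499 in OCI-AML3, 1373 to 1542 in SKM-1, 3898 to 4539 for the panel, 11 to 27 common to all lines, 159 to 449 for MOLM-13 against MOLM-14 and 1636 to 2277 differing between lines. Of 20 gene lists 11 to 14 were called (12 with all libraries), of the marker lists 5, and of the named genes 103 to 112.

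Of the values that reversed, DCK and KIT in MOLM-13 and SKM-1 alone passed the threshold there (limma, BH-adjusted p = 0.000994 and 0.0253). For the gene list: decitabine uptake and metabolism, the median was -0.0093 without a filter, -0.0145 under the stricter one, -0.0760 without KG-1, -0.0076 without OCI-AML3, -0.1800 in MOLM-13 and SKM-1 alone, -0.0659 with weights and -0.0677 without shallow libraries. Leaving out 1 library it lay between -0.0606 and 0.0452, and turned without KG-1 DMSO replicate 2 (-0.0569), KG-1 decitabine replicate 2 (-0.0195), MOLM-14 DMSO replicate 2 (-0.0606), MOLM-14 decitabine replicate 2 (-0.0155), OCI-AML3 decitabine replicate 1 (-0.0038) or 2 (-0.0031) or SKM-1 decitabine replicate 3 (-0.0037). DCK had -0.1458 without KG-1, -0.0076 without OCI-AML3, -0.2905 in MOLM-13 and SKM-1 alone, -0.0659 with weights, -0.1167 without shallow libraries and -0.1051 to 0.0983 leaving out 1 library, turning without KG-1 DMSO replicate 2 (-0.0059), KG-1 decitabine replicate 2 (-0.1051) or OCI-AML3 decitabine replicate 1 (-0.0038). For the gene list: erythroid markers, it was 0.0675 without a filter, 0.2510 without OCI-AML3, 0.1581 in MOLM-13 and SKM-1 alone, 0.1863 with weights, 0.1980 without shallow libraries and -0.2777 to 0.1024 leaving out 1 library, turning without MOLM-14 DMSO replicate 3 (0.0843), MOLM-14 decitabine replicate 2 (0.0635) or OCI-AML3 decitabine replicate 2 (0.1024). The gene list: m6A pathway turned to 0.0066 under quantile normalization and 0.0090 scaled without mitochondrial genes. The gene list: cholesterol synthesis turned to 0.0138 without MOLM-13, 0.0683 without SKM-1, 0.1108 in KG-1, MOLM-14 and OCI-AML3 alone and 0.0076 scaled without mitochondrial genes. The gene list: double-stranded RNA and DNA sensors turned to -0.0114 without MOLM-14, -0.0519 without SKM-1 and -0.0498 in KG-1, MOLM-14 and OCI-AML3 alone, where the gene list: mitosis genes turned to 0.0286. Without MOLM-14, KIT had -0.1283, CLDN4 0.0752, FBN1 -0.0773 and SLC29A1 0.0302. COL1A2 had -0.0128 without OCI-AML3, IFI16 -0.1724 and IGF2BP3 -0.1358 without SKM-1, and in KG-1, MOLM-14 and OCI-AML3 alone these had -0.1805, -0.1751 and -0.1799. In MOLM-13 and SKM-1 alone TLR3 had 0.1896, STARD4 -0.1162, KIT -0.5791, CLDN4 0.4425 and FBN1 -0.2717, and the gene list: haematopoietic progenitor markers -0.0701. FBN1 had -0.2063 with weights and -0.3684 without shallow libraries.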

Other observations

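The comparison of the 2 correlations of MOLM-13 and the standard errors of the correlations were chosen only after the result was seen, and so were some of the germline genes left out below (TKTL1 and the PNMA genes). On the panel mean, 8.20% of 1708 long intergenic noncoding genes were called higher and 0.820% lower, and 6.46% of 1532 antisense genes were higher and 1.04% lower. Of 15127 protein-coding genes 14.9% were higher and 10.5% lower, and of 1011 processed pseudogenes 1.88% and 1.39%. The difference between these kinds of gene was not tested.

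Genes of chromosome X were called higher more often in SKM-1: 12.3% of 721 against 5.57% of 20853 genes on the other chromosomes (Fisher's exact test over genes, odds ratio 2.39, BH-adjusted p = 1.45e-10 over 12 tests). In KG-1, MOLM-13, MOLM-14 and OCI-AML3 the odds ratios were 0.869, 1.25, 1.0 and 1.14 (Fisher's exact test, BH-adjusted p = 0.818, 0.818, 0.938 and 0.818). The hypothesis that cancer-testis genes alone account for this was tested by leaving out the germline families. The share on X was then 8.02% of 673 genes against 5.53% (odds ratio 1.49, confidence interval 1.1 to 1.99, Fisher's exact test, BH-adjusted p = 0.0323), so the families left out do not account for all of it. Any cancer-testis genes outside these families were kept, so the test cannot decide for cancer-testis genes at large. On the panel mean 120 of 721 X genes were higher against 2512 of 20853 others with them (odds ratio 1.46, BH-adjusted p = 0.00239), and 85 of 673 against 2504 of 20830 without them (odds ratio 1.06, BH-adjusted p = 0.818). Neighbouring genes are not independent, so these p-values may be too small.

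Across genes the fold changes of MOLM-13 correlated more with those of SKM-1 (r = 0.251) than with those of its sister line MOLM-14 (r = 0.171). The hypothesis that noise of the shallower MOLM-14 libraries accounts for this was tested by removing the spread between replicates from the variances. The sister pair then had 0.575 and MOLM-13 with SKM-1 0.349 (difference 0.226, jackknife SE 0.0399 over 23 chromosomes), so the order turned, and noise may account for it. In MOLM-14 the spread removed was 0.694 of a variance of 0.816. The jackknife leaves out chromosomes and not libraries, so its SE does not include the error of that spread, and the order is uncertain. The prediction written beforehand had asked for the highest rank of the 10 pairs, and the sister pair ranked behind MOLM-14 and OCI-AML3, with 0.809 (difference 0.234, jackknife SE 0.0562). That bound was set wrongly, as a pair without MOLM-13 has no bearing on the order of its 2 correlations.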
